A study of Ciona savignyi with 56 samples.

How the data were processed

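Polyadenylated RNA of single blastomeres was measured by a modified Smart-seq2 protocol with barcoded primers. Per the labels, cells were picked by glass capillary from single embryos dissociated with trypsin, cDNA of cells of the same stage was pooled, and pools were made into libraries by tagmentation. Untreated embryos covered the 1-, 2-, 4-, 8-, 16-, 32-, 64- and 110-cell stages, and a further group of 64-cell embryos grew with U0126, an inhibitor of MEK, the kinase that carries the signal of fibroblast growth factor (FGF) receptors.

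The deposited matrix holds whole-number counts for 12172 genes in 773 cells, and the authors' cell table gives each cell its library, embryo, stage, class, read number, UMI number and gene number. UMIs are molecular tags that mark the copies of 1 molecule. The matrix is called a UMI matrix, but its unit was tested against the cell table. In 518 cells the matrix total equalled the table's UMI number exactly, so these columns are UMI counts. In the other 255 cells the matrix total equalled the table's read number exactly, so these columns are read counts. The number of genes with a count equalled the table in 518 of the 518 cells with UMIs and in 0 of the 255 with reads, where the summed gene numbers were 1.07 to 1.11 times those of the table by group, so these columns may differ in more than the unit. The submitters' processing notes name CASAVA 1.8, DESeq2 and Seurat. The aligner, the genome build, the annotation and the way in which cell classes were assigned are not given in the sources used here. The files pair no gene identifier with a name, so genes are given by identifier, and 0 identifiers could be matched to the marker lists written beforehand.

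The replicate was the embryo. GEO lists 56 entries for 41 libraries, and the 15 repeat entries carry the barcodes of a library already listed, so each was counted with that library. No embryo number occurs in more than 1 group. Counts were summed over the cells of an embryo for comparisons between stages, and over the cells of an embryo and class for comparisons between classes. Cells labelled low quality were kept in the sums per embryo and left out of all work on classes.

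Comparisons between stages used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a quasi-likelihood fit of all untreated stages, and Benjamini-Hochberg adjustment over all tested genes at 0.05. U0126 was compared with untreated 64-cell embryos in a fit of those 5 embryos. Comparisons between classes of a stage used the same test with the embryo as a blocking term, so that every contrast was taken within embryos. The difference of a class contrast between untreated and treated embryos was tested by the interaction of class and treatment, after merging the untreated classes into the 8 classes of the treated embryos. Alternatives used DESeq2 1.42.0, limma 3.58.1, RLE scaling, other filters on low counts, a log2 threshold of 1, and leaving out each embryo in turn. The limma-trend alternative took sums of cells scaled to the same total, as log2 CPM with a prior count of 2. It had no TMM scaling and another filter, so it differs from the main fit in more than the test. Single values per embryo were compared by exact two-sided permutation tests over embryos with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

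Genes per cell were counted after thinning every cell to 10000 counts (alternatives 5000 and 20000). Variation between cells of an embryo was the percent of genes with a variance above 2 times the mean among genes with at least 20 counts (alternative 100), in embryos with at least 8 cells. For class contrasts under U0126, the 50 genes with the largest contrast in 2 untreated embryos were measured in the remaining untreated embryo and in the treated embryos, as log2 of CPM with a pseudocount of 10 (alternative 40). This measure was tested on simulated data with planted contrasts kept by 100%, 50% and 0% in treated embryos, where it returned 100%, 48.1% and 4.27%. The planted contrasts were larger than the measured ones and every simulated class had the same depth, so these values do not give the accuracy on the real contrasts. Class profiles were compared by Pearson correlation over the 300 genes that vary most between classes (alternative 1000), always with other embryos as the reference.

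The tests of the stage steps, of U0126, of class shares, of depth and of variation, with most of their alternatives, were chosen before the data were examined. The comparisons between classes of a stage, the steps from the 4-cell to the 64-cell, the 1-cell to the 8-cell and the 8-cell to the 32-cell stage, the held-out contrasts, the class profiles, the posterior genes and the genes of neighbouring identifiers were chosen after the data had been seen. Genes were named by a rule fixed beforehand: adjusted p under 0.05, every embryo of a group above every embryo of the other in CPM, and the largest fold changes, at most 2 identifiers in each direction. Where a group had no count, the fold is a lower bound, the mean normalised CPM of the other group over a floor of 3 counts in the TMM-scaled totals of the group without counts. Reads without molecular tags are not independent molecules, so floors cover counting error only. In class comparisons, the called gene with the largest change in each direction was named.

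Total counts per embryo ran from 169789 to 465522 reads at the 1-cell stage, 91754 to 214900 UMIs at the 2-cell stage, 327876 to 384149 UMIs at the 4-cell stage and 2030096 to 2636561 reads at the 8-cell stage. They were 3966261 and 4078922 reads at the 16-cell stage, 8697598 and 8711841 reads at the 32-cell stage, 2372200 to 2765860 UMIs at the 64-cell stage and 2886511 to 4303758 UMIs at the 110-cell stage. The 2 treated embryos held 10768923 and 11770147 reads. On simulated counts for 6067 genes, the comparison of the 64-cell with the 110-cell stage recovered 64% of planted 2-fold changes and 100% of planted 4-fold changes. The comparison with U0126 recovered 28% and 97% of those planted among 7542 genes, each at a dispersion of 0.05. That dispersion was set, not estimated, and all simulated embryos were drawn from a single profile without a difference in the kind of count. Changes were planted only in genes with enough expected counts. Real 64-cell embryos 1 and 3 had 23 genes more than 8-fold apart, so these percents do not give the recovery in the real data. The interaction test recovered 3% of planted 4-fold and 18% of planted 8-fold differences between contrasts among 6208 genes at a dispersion of 0.2.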

Results

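Blastomeres of the ascidian Ciona savignyi were measured as single cells, from the zygote to the stage of 110 cells, in embryos whose cleavages follow a fixed lineage. The matrix covered 773 cells of 31 embryos, 29 of them untreated. There were 8 embryos (8 cells) at the 1-cell stage, 5 embryos (10 cells) at the 2-cell stage, 3 embryos (12 cells) at the 4-cell stage and 3 embryos (24 cells) at the 8-cell stage. There were 2 embryos (32 cells) at the 16-cell stage, 2 embryos (66 cells) at the 32-cell stage, 3 embryos (179 cells) at the 64-cell stage, 3 embryos (317 cells) at the 110-cell stage and 2 embryos (125 cells) at the 64-cell stage with U0126. The authors gave 742 cells a class and marked 31 as low quality. Of 12172 genes, 11774 had a count in some cell. The files do not pair the gene identifiers with names.

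The median cell held 118776 UMIs at the 1-cell stage, 69921 at the 2-cell, 87960.5 at the 4-cell, 95985.5 at the 8-cell, 61775 at the 16-cell, 59989 at the 32-cell, 36433 at the 64-cell and 29297 at the 110-cell stage, and 37493 with U0126, by the authors' cell table. Per embryo, the median fell from 127440 ± 36164 (SD, n = 8) at the 1-cell stage to 28806 ± 3147 (n = 3) at the 110-cell stage (exact two-sided permutation p = 0.00606, the smallest this design allows). Thinned to 10000 counts, a zygote showed 3191 ± 88.5 genes (n = 8) and a 2-cell blastomere a mean of 3590 (n = 5; exact two-sided permutation p = 0.000777, the smallest possible). The zygotes' columns are reads and those of the 2-cell stage are UMIs.

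The matrix mixed reads and UMIs by stage. All cells of the 2-, 4-, 64- and 110-cell stages held UMI counts, and all cells of the 1-, 8-, 16- and 32-cell stages and of the U0126 embryos held read counts. The 15 libraries with read counts were exactly the 15 that GEO lists with a repeat entry, among 41 libraries. Reads per UMI in the cell table ran from 2.56 in the median 1-cell column to 9.11 at the 110-cell stage. Steps between stages in the same kind of count are therefore given first, and contrasts between classes were taken within embryos, where the kind of count is the same.

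**Figure D1:**
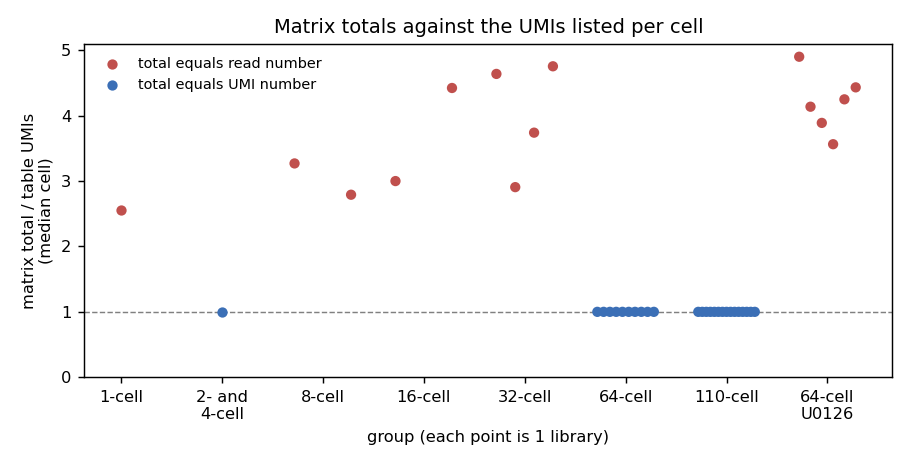
Matrix total of the median cell divided by its UMI number in the authors' cell table, for each of the 41 libraries (points) by group. The 26 libraries with UMI counts sit at 1, and the 15 libraries with read counts sit at 2.56 and above.

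The step from the 4-cell to the 64-cell stage, both in UMIs and 3 embryos each, asks which transcripts appear and which are lost across cleavage. Of 6441 genes tested, 330 rose and 304 fell. All 4-cell embryos were in a single library, which held no 64-cell embryo, so that stage and library coincide. ENSCSAVG00000004666 had no UMI in 4-cell embryos and reached 195 ± 21.6 normalised CPM (SD, n = 3) at the 64-cell stage, at least 77.5-fold higher (log2 fold change 11.58, SE 0.97, adjusted p 9.76e-07). ENSCSAVG00000011320 went from 0 to 82.9 ± 23.1 CPM, at least 33.0-fold higher (adjusted p 0.000241). ENSCSAVG00000009195 went from 24.0 ± 4.68 CPM to 0, at least 66.2-fold lower (log2 fold change -8.61, SE 1.46, adjusted p 0.000494). The count was 413, 395 and 362 without 4-cell embryo 1, 2 or 3, and 397 with a log2 fold change of at least 1.

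The step from the 8-cell to the 32-cell stage, both in reads (3 and 2 embryos), shared no embryo with the step above. Here 77 genes rose and 13 fell. Of the 77 risen genes, 53 had also risen from the 4-cell to the 64-cell stage, where 3.95 would be shared by chance, and 10 of the 13 fallen genes had also fallen, where 0.614 would. No gene was called in opposite directions in the pair of steps. Across the 6441 genes, which are not independent replicates, the changes of the pair of steps correlated with Pearson r 0.437 and Spearman rho 0.254. ENSCSAVG00000004666 rose from 0 to 49.7 ± 4.66 CPM (n = 2), at least 113-fold (log2 fold change 9.58, SE 0.76, adjusted p 6.39e-07). ENSCSAVG00000000147 fell from 37.4 ± 14.7 to 9.88 ± 3.87 CPM (log2 fold change -1.92, SE 0.48, adjusted p 0.0300). The count of 90 dropped to 57 and 58 without 8-cell embryo 1 or 2 and to 50 without 32-cell embryo 2. It was 157 with DESeq2 and 24 with limma-trend.

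**Figure D2:**
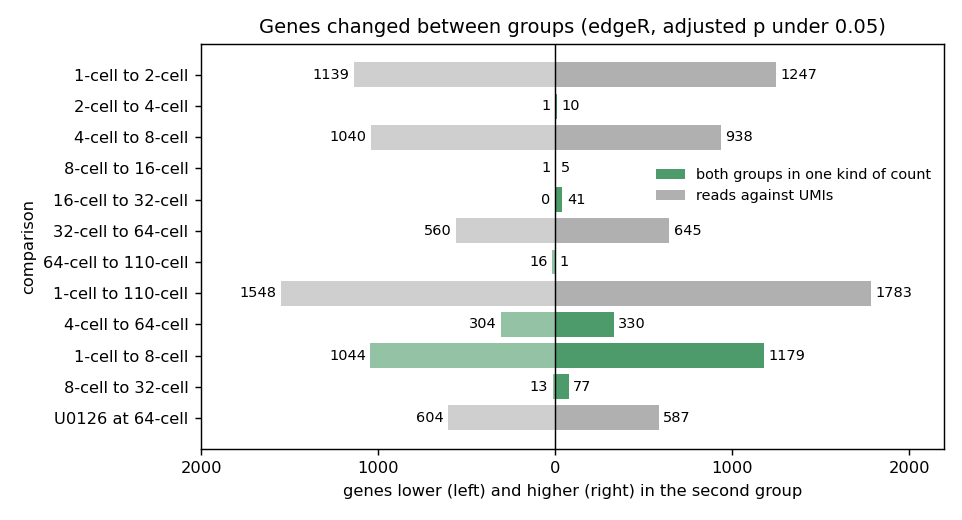
Genes higher (right) and lower (left) in the second group of each comparison, by edgeR at an adjusted p under 0.05, with bars from 0 and counts printed. Green bars compare groups in the same kind of count and grey bars compare reads with UMIs.

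The 53 genes that rose in the pair of steps differed between classes in the 110-cell embryos, which entered neither step. Their median variance between classes shared by pairs of embryos was 1.69, against 0.0185 for random genes of the same level, and none of 1000 random lists passed 0.106. For all 330 genes that rose from the 4-cell to the 64-cell stage it was 0.0582, against 0.0153 for random genes (0 of 1000 lists as high), and for the 304 genes that fell in that step 0.00995, reached by 730 of 1000 random lists. At the 64-cell stage the 53 risen genes peaked in epidermis (15 genes), endoderm (11), animal neural cells (8), notochord (5) and muscle (5).

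From the 16-cell to the 32-cell stage (reads, 2 embryos each) 41 genes rose and 0 fell by edgeR, 184 genes passed an unadjusted p of 0.05, and DESeq2 called 38 higher and 3 lower. ENSCSAVG00000004666 was absent from the 2 embryos with 16 cells and reached 49.7 ± 4.66 CPM, at least 131-fold higher (adjusted p 3.00e-06). ENSCSAVG00000010941 rose from 0 to 12.1 ± 1.55 CPM, at least 31.9-fold (adjusted p 3.82e-05). Without 16-cell embryo 1 the count was 22, it was 11 in a fit of read-count stages alone, and limma-trend called 5.

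From the 8-cell to the 16-cell stage (reads) 5 genes rose and 1 fell. ENSCSAVG00000010582 rose to 63.7 ± 29.5 CPM (n = 2; log2 fold change 5.23, SE 0.92, adjusted p 0.00441). ENSCSAVG00000007605 fell from 9.19 ± 6.67 to 0.761 ± 0.368 CPM (log2 fold change -3.48, SE 0.71, adjusted p 0.0278). The count was 14 without 8-cell embryo 3, 3 without 16-cell embryo 2, 15 with DESeq2 and 0 with limma-trend.

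From the 2-cell to the 4-cell stage (UMIs, a single library) 10 genes rose and 1 fell. ENSCSAVG00000007450 rose from 28.3 ± 7.35 (n = 5) to 75.1 ± 14.5 CPM (n = 3; log2 fold change 1.43, SE 0.31, adjusted p 0.0476), and ENSCSAVG00000004583 fell from 315 ± 72.7 to 124 ± 26.6 CPM (log2 fold change -1.32, SE 0.26, adjusted p 0.0193). The count of 11 was 17, 5 and 6 without 2-cell embryo 1, 3 or 5, and 2 and 3 without 4-cell embryo 2 or 3. DESeq2 called 33 higher and 22 lower, and limma-trend 36 and 22.

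From the 64-cell to the 110-cell stage (UMIs, 3 embryos each) 1 gene rose and 16 fell. ENSCSAVG00000004614 rose from a mean of 2.44 to 35.9 ± 16.8 CPM (log2 fold change 3.78, SE 0.67, adjusted p 0.0225), and ENSCSAVG00000010996 fell from 31.2 ± 3.50 to 0.719 ± 0.857 CPM (log2 fold change -5.52, SE 0.81, adjusted p 0.00201). The count was 55, 5 and 100 without 64-cell embryo 1, 2 or 3, and 57 and 3 without 110-cell embryo 1 or 3. DESeq2 called 10 higher and 53 lower and limma-trend 19 and 21, and whole embryos were no more alike within a stage (mean r 0.919 over 6 pairs) than between these stages (0.921 over 9 pairs).

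From the 1-cell to the 8-cell stage, both in reads, 1179 genes rose and 1044 fell (8 and 3 embryos). ENSCSAVG00000006617 had no read in 8 zygotes and 117 ± 17.1 CPM (n = 3) at the 8-cell stage, at least 90.4-fold higher (adjusted p 0.000160). ENSCSAVG00000011973 went from 39.7 ± 56.0 CPM to 0, at least 90.4-fold lower (adjusted p 4.55e-05). Of the genes that fell from the 4-cell to the 64-cell stage, 94 had also fallen here, where 49.3 would by chance. All zygotes were in a single library, so that stage and library coincide. Limma-trend called 1325 higher and 382 lower.

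The remaining planned steps set reads against UMIs, so their changes hold the stage and the kind of count together. From the 1-cell to the 2-cell stage 1247 genes were higher and 1139 lower, with 2428 and 1032 by limma-trend, and ENSCSAVG00000001650 rose from 0 to 21.9 ± 14.0 CPM, at least 16.9-fold (adjusted p 0.00149). From the 4-cell to the 8-cell stage 938 were higher and 1040 lower, with 511 and 855 by limma-trend, and ENSCSAVG00000009870 rose from 0 to 182 ± 17.9 CPM, at least 72.4-fold (adjusted p 0.000306). Without 4-cell embryo 3 that count of 1978 was 1317. From the 32-cell to the 64-cell stage 645 were higher and 560 lower, with 308 and 178 by limma-trend, and 536 and 526 genes were called without 32-cell embryo 1 or 2. ENSCSAVG00000006848 rose from 0 to 35.1 ± 7.03 CPM there, at least 200-fold (adjusted p 1.11e-05). Genes that rose into the read counts of the 8-cell stage fell out of them at the 64-cell stage in 393 cases, where 81.6 would by chance.

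The comparison of the first with the last stage asks which transcripts of the egg had been replaced by the 110-cell stage, and also set reads against UMIs. It called 1783 genes higher and 1548 lower, with 2586 and 713 by limma-trend. ENSCSAVG00000004666 rose from 0 in 8 zygotes to 146 ± 65.7 CPM (n = 3), at least 112-fold (adjusted p 1.47e-09), and ENSCSAVG00000012499 fell from 1241 ± 768 to 41.9 ± 23.9 CPM (log2 fold change -4.98, SE 0.52, adjusted p 1.79e-09). ENSCSAVG00000012499 lies in the run of neighbouring identifiers described below. The mean share of that run was at least 12.5% in every group with reads and at most 7.42% in every group with UMIs. The fall of this gene can therefore not be told apart from the kind of count. ENSCSAVG00000004666 was absent from all embryos up to the 16-cell stage in either kind of count.

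**Figure D3:**
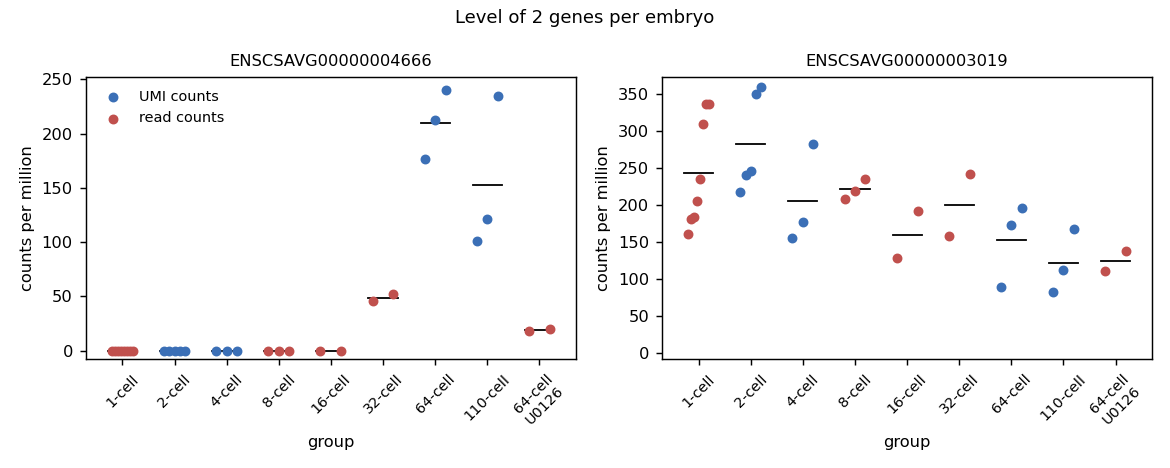
CPM of ENSCSAVG00000004666 and ENSCSAVG00000003019 per embryo (points) with the mean (line), by group and kind of count. The first gene is at 0 up to the 16-cell stage and at 101 or more in each 64-cell and 110-cell embryo, and the second is present in every group.

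At the 4-cell stage the blastomeres A (anterior) and B (posterior) were compared in 3 embryos, which asks what the egg's posterior region passes to B. All 15 called genes of 3930 were higher in B. The largest contrast was that of ENSCSAVG00000001907 (log2 A over B -4.27, SE 0.51, adjusted p 4.86e-14). Of the 15 genes, 10 lie in a run of neighbouring identifiers described below, and the largest log2 contrast among these was -1.11. The count was 8 without 4-cell embryo 3, 8 with DESeq2 and 5 without the run.

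The 15 genes were then followed in the class that holds the germline precursor, against the mean of the other classes of the same embryo. The mean of the list was higher in 12 of 12 later untreated embryos, by a log2 of 1.65 ± 0.68 (SD; exact two-sided sign-flip p 0.000488, the smallest possible). Single genes differed: 3 of the 15 were higher in all 12 embryos, 5 of 15 were higher in 64-cell embryo 1 and 4 of 15 in 110-cell embryo 3, and without the 4 genes of the largest contrast at the 4-cell stage the mean was 0.52 (exact two-sided sign-flip p 0.147). The mean was 1.76 ± 0.18 in B4.1 at the 8-cell stage, 1.90 ± 0.07 in B5.2, 2.58 ± 0.10 in B6.3, 1.11 ± 0.70 in B7.6 at the 64-cell stage and 1.13 ± 0.80 in B7.6 at the 110-cell stage. The 5 genes outside the run stood at 3.65 ± 1.16, again in 12 of 12 embryos (exact two-sided sign-flip p 0.000488). Over the sister class, the whole list stood at 1.43 ± 0.04 in B5.2, 1.70 ± 0.05 in B6.3, 0.24 ± 1.11 in B7.6 at the 64-cell and -0.01 ± 0.94 at the 110-cell stage, so it did not separate B7.6 from B7.5 (over all stages 0.75 ± 1.00, higher in 6 of 9 embryos, exact two-sided sign-flip p 0.0625). The mean of the 5 genes outside the run was higher than in the sister class in 9 of 9 embryos (3.22 ± 1.32; exact two-sided sign-flip p 0.00391, the smallest possible). Over the other classes, the strongest single genes in the 12 embryos were ENSCSAVG00000003019 (5.93 ± 1.89) and ENSCSAVG00000001907 (5.73 ± 1.73), while ENSCSAVG00000008691, also outside the run, stood at -0.92 and was higher in 2 of the 12. These genes were chosen after their values were seen. The way in which classes were assigned is not given, so use of such genes in the labels cannot be told apart from passage along the lineage.

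A run of 42 genes with identifiers within 30 of that of the most abundant gene, ENSCSAVG00000012509, took a share of counts that differed between classes. At the 8-cell stage it took 26.3 ± 3.52% of reads in B4.1 and 11.3 ± 0.687% in the class named animal (SD, n = 3). At the 32-cell stage the share was 28.5 ± 1.19% in B6.3, 26.7 ± 1.37% in B6.2, 19.6 ± 0.437% in B6.4 and 14.2 ± 2.01% in A6.2/4 (n = 2), against 4.59 ± 0.0104% in A6.1/3 and 4.26 ± 0.358% in B6.1. At the 64-cell stage the muscle classes B7.4 and B7.8 led with means of 18.6% and 17.0% of UMIs and the endoderm class A7.1/2/5 had 2.80 ± 1.17% (n = 3). The germline class B7.6, a daughter of B6.3, had 4.69 ± 0.907% (n = 2), below its sister B7.5 with a mean of 10.5% and below epidermis with 4.97 ± 2.35%. At the 110-cell stage the muscle classes B8.7/8 and B8.15/16 held 20.6 ± 5.29% and 19.2 ± 8.56%, against 2.98 ± 1.52% in endoderm. The low share of B7.6 was not seen at this stage. It held 10.0 ± 6.96% (n = 3), beside 11.2 ± 2.71% in B7.5 and means of 3.89% and 4.11% in anterior and posterior epidermis. What these genes encode is not given in the files.

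**Figure D4:**
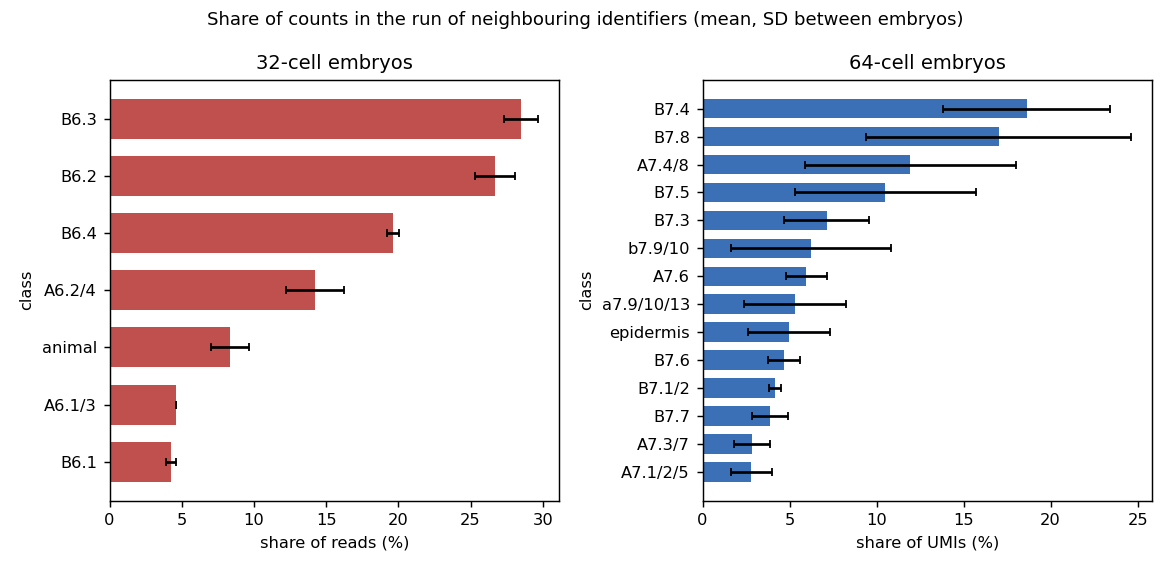
Share of counts in the run of neighbouring identifiers per class, as the mean and SD between embryos, in reads at the 32-cell stage (2 embryos) and in UMIs at the 64-cell stage (2 or 3 embryos). Posterior vegetal and muscle classes lead at the 32-cell and the 64-cell stage, and the endoderm classes B6.1 and A7.1/2/5 are lowest at the 32-cell and the 64-cell stage.

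At the 8-cell stage, B4.1 differed from the class named animal (18 of 24 cells, so more than animal blastomeres) by 52 genes higher and 18 lower of 6367. ENSCSAVG00000003019 was higher in B4.1 (log2 5.30, SE 0.16, adjusted p 3.22e-217). At the 16-cell stage B5.1, which leads to endoderm, mesenchyme and muscle, and its sister B5.2 on the germline side differed by 20 genes higher and 17 lower, with ENSCSAVG00000007674 higher in B5.2 (log2 -6.51, SE 0.92, adjusted p 3.93e-05). A5.1/2 had 25 genes below B5.1 and none above, 17 of them in the run. Other fits called genes above B5.1: 6 of 52 with only the 2 classes, 2 of 32 with any count and 1 of 20 with DESeq2. RLE scaling called none above. Between A5.1/2 and the animal cells edgeR called 0 genes and DESeq2 0, with 32 at an unadjusted p under 0.05.

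At the 32-cell stage most genes called between endoderm precursors and their sisters lay in the run. A6.1/3 and A6.2/4, sisters that lead to endoderm and to notochord and nerve cord, differed by 17 genes, all higher in A6.2/4 and all 17 in the run. B6.1 and B6.2, sisters that lead to endoderm and to mesenchyme and muscle, differed by 19 genes, all higher in B6.2 and 18 in the run. With the run left out edgeR called 0 genes in each pair, with 120 and 342 at an unadjusted p under 0.05. Fits with the run also called genes higher on the endoderm side: DESeq2 3 of 21 for A6.1/3 and 3 of 27 for B6.1, a fit of A6.1/3 and A6.2/4 alone 4 of 27, and a fit of genes with any count 6 of 29 for B6.1. B6.3, the germline precursor, had 35 genes above its sister B6.4 and 7 below. ENSCSAVG00000001907 was higher in B6.3 (log2 6.93, SE 0.53, adjusted p 4.22e-12), and ENSCSAVG00000004666 lower (-9.40, SE 1.52, adjusted p 0.000160).

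At the 64-cell stage, notochord precursors A7.3/7 and their nerve cord sisters A7.4/8 differed by 16 genes higher and 22 lower of 5162 (8 and 11 cells, 3 embryos). ENSCSAVG00000003189 was higher in notochord (log2 8.04, SE 1.17, adjusted p 5.89e-07) and ENSCSAVG00000005021 in nerve cord (-4.67, SE 1.03, adjusted p 0.00307). Of the 22 genes higher in nerve cord, 17 were in the run, and none of the 16 higher in notochord was. Mesenchyme against muscle gave 9 higher and 25 lower for B7.3 against B7.4, and 9 and 36 for B7.7 against B7.8. ENSCSAVG00000003189 was also higher in B7.3 over B7.4 (log2 6.52, SE 1.42, adjusted p 0.00421), and ENSCSAVG00000011378 in B7.7 over B7.8 (8.24, adjusted p 0.000171). Of the muscle-side genes, 18 of 25 and 17 of 36 were in the run. Counts changed to 25 without 64-cell embryo 1 (from 38), to 19 without embryo 3 (from 34) and to 29 without embryo 1 (from 45). Without the run they were 21, 15 and 23.

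Endoderm A7.1/2/5 against trunk lateral cells A7.6 gave 14 higher and 21 lower at the 64-cell stage, 14 of the latter in the run, with ENSCSAVG00000005749 higher in endoderm (log2 7.71, SE 1.41, adjusted p 0.000711). Anterior and posterior endoderm (A7.1/2/5 against B7.1/2) differed by 17 genes, 15 of them higher in B7.1/2, led by ENSCSAVG00000001326 (-6.11, SE 0.76, adjusted p 2.60e-08), where DESeq2 called 1 gene. B7.6 (germline) had 12 genes above B7.5 (heart and trunk ventral precursors) and none below, from 3 cells of each class in 2 embryos. With any count, 7 of 20 called genes were higher in B7.5, and without 64-cell embryo 3, which held no cell of this pair, it was 2 of 14. Without embryo 2, which leaves only embryo 1 with cells of the pair, some called genes were also higher in B7.5. DESeq2 and RLE scaling called none higher in B7.5. Neural a7.9/10/13 and b7.9/10 differed from epidermis by 10 and 15 genes, with ENSCSAVG00000006812 higher in b7.9/10 (5.66, SE 0.80, adjusted p 6.50e-07). Without 64-cell embryo 1, 2 or 3 the endoderm against trunk lateral count was 21, 4 and 21. Without embryo 1 or 2 the endoderm pair gave 3 and 34, without embryo 2 or 3 the neural contrasts gave 6 and 4 for a7.9/10/13 and 7 and 6 for b7.9/10, and without embryo 1 the germline contrast gave 7.

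At the 110-cell stage, notochord A8.5/6/13/14 and nerve cord A8.7/8 differed by 40 genes higher and 30 lower of 5159 (20 and 11 cells), 15 of the latter in the run. ENSCSAVG00000003890 was higher in notochord (log2 7.79, SE 1.56, adjusted p 0.000608) and ENSCSAVG00000003849 in nerve cord (-7.19, SE 1.70, adjusted p 0.00775). The nerve cord classes A8.7/8 and A8.15/16 differed by 7 genes and the muscle classes B8.7/8 and B8.15/16 by 26, with ENSCSAVG00000003997 higher in B8.15/16 (-8.88, SE 1.02, adjusted p 1.27e-09). B8.6, the secondary notochord precursor, differed from its mesenchyme sister B8.5 by 14 genes (13 higher) and from primary notochord by 8. B7.5 and B7.6 differed by 66 genes, with ENSCSAVG00000003019 higher in B7.6 (-5.76, SE 0.49, adjusted p 2.20e-16). Without 110-cell embryo 3 the notochord contrast gave 30, the nerve cord pair 2, and B7.5 against B7.6 26. Without embryo 2 the muscle pair gave 8 and B7.5 against B7.6 27. B8.6 against B8.5 gave 6 and 7, and B8.6 against primary notochord 2 and 1, without embryo 2 or 3, and DESeq2 called 3 for the nerve cord pair and 3 for B8.6 against primary notochord.

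In the ectoderm of the 110-cell stage, neural a8.17/18/19/20/25/26 had 26 genes above anterior epidermis and 13 below, led by ENSCSAVG00000000423 (log2 5.18, SE 1.00, adjusted p 0.000286). Neural b8.17-20 had 29 genes above posterior epidermis and 15 below. ENSCSAVG00000006812, higher in b7.9/10 at the 64-cell stage, led here too (7.59, SE 0.69, adjusted p 1.69e-14). Anterior and posterior epidermis differed by 9 genes higher and 6 lower, led by ENSCSAVG00000002442 (3.80, SE 0.64, adjusted p 3.90e-05). The count for a8.17/18/19/20/25/26 was 25 without 110-cell embryo 2, and that between the epidermis classes was 7 without embryo 3.

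Class profiles were set beside those of other embryos. At the 64-cell stage 14 of 14 classes resembled their own class most in other embryos, at the 110-cell stage 15 of 16 and at the 32-cell stage 6 of 7. With 1000 genes in place of 300, 9 of 14 did at the 64-cell stage. Of the 11 classes of the 110-cell stage with new blastomere names, 9 resembled their mother class of the 64-cell stage most, and of the 5 that keep the names of the 64-cell stage 4 resembled the class of that name most. The exceptions were notochord A8.5/6/13/14 (r 0.49 with endoderm A7.1/2/5 and 0.43 with its mother A7.3/7), B7.5 (0.54 with B7.8 and 0.39 with B7.5) and B8.6. The secondary notochord class B8.6 had r 0.11 with its mother B7.3, and its highest values were 0.251 with endoderm A7.1/2/5 and 0.246 with notochord A7.3/7. These correlations run across genes, which are not independent replicates.

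U0126 blocks the MEK step of FGF signalling, which notochord needs against nerve cord and mesenchyme against muscle, so the comparison asks which class contrasts depend on it. The contrast of notochord genes over nerve cord was smaller in the treated embryos. Genes picked in other untreated embryos stood at a mean log2 of 0.79 ± 0.11 (SD, n = 3) for A7.3/7 over A7.4/8 without the drug and at 0.10 ± 0.07 (n = 2) with it, 12.7% of the contrast (exact two-sided permutation p = 0.1, the smallest possible). Embryo 3 without the drug held 1 cell of A7.3/7. The percent kept was 23.5 with 100 genes and 23.7 with a pseudocount of 40, and with the run left out 0.77 ± 0.12 became -0.03 ± 0.04. Mesenchyme over muscle (B7.3/7 over B7.4/5/8) went from 0.88 ± 0.04 to 0.23 ± 0.06, or 25.8% (exact p = 0.1), and from 0.87 ± 0.04 to -0.01 ± 0.10 without the run. This loss depended on the settings: 67.5% was kept with 100 genes (exact p = 0.1) and 77.7% with a pseudocount of 40 (exact p = 0.4). Endoderm with trunk lateral cells over animal cells (A7.1/2/5/6) went from 1.87 ± 0.04 to 0.75 ± 0.02, or 40.3% (exact p = 0.1).

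Among the classes measured over animal cells, B7.4/5/8 kept the most. It is called muscle here, although it also holds B7.5, the heart and trunk ventral precursors. B7.6 was not in this measure. B7.4/5/8 over animal cells was 2.20 ± 0.09 without and 2.06 ± 0.24 with the drug (93.6%, and 85.0% after thinning the treated cells, exact two-sided permutation p = 0.1, the smallest possible), animal over A7.1/2/5/6 stood at 101%, and A7.4/8 over animal at 77.5% (68.1% after thinning, exact p = 0.1). Other classes over animal cells kept less: B7.1/2 58.8%, B7.3/7 47.8% and A7.3/7 33.0% (exact two-sided permutation p = 0.1 each, the smallest possible). Muscle over mesenchyme kept 65.8% and nerve cord over notochord 42.5% (exact two-sided permutation p = 0.4 and 0.2). Of the 17 genes higher in untreated nerve cord than in notochord, 16 were also called in treated embryos, and 16 of the 17 were in the run. Of the 62 genes higher in muscle than in animal cells, 59 were also called in treated embryos, as were 35 of the 38 outside the run. Of the 25 genes higher in A7.1/2/5/6 than in animal cells, 10 were, and their median log2 contrast was 4.99 without and 2.13 with the drug. A7.4/8 over A7.3/7 kept 25.6% with 100 genes and 15.6% without the run.

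**Figure D5:**
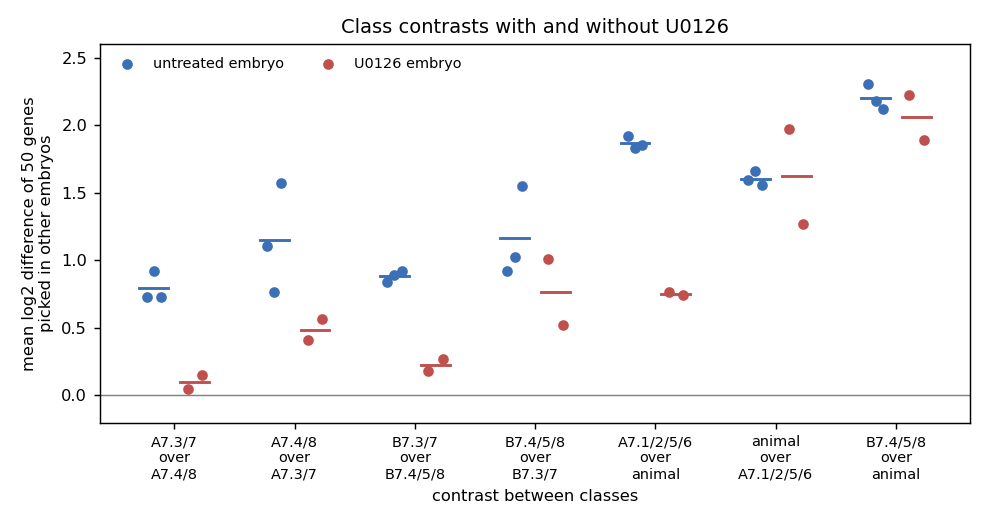
Mean log2 difference between 2 classes over 50 genes picked in other untreated embryos, for each untreated (blue) and U0126 (red) embryo, with the mean as a line. Notochord over nerve cord (A7.3/7 over A7.4/8) is near 0 with U0126, and muscle over animal cells is at 93.6% of its untreated mean.

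The interaction test of single genes called 3 genes for notochord against nerve cord, 2 for mesenchyme against muscle and 1 for A7.1/2/5/6 against animal cells. In this edgeR fit the largest counts were those of posterior endoderm B7.1/2 (10) and mesenchyme B7.3/7 (7) against animal cells, with 1 each for A7.3/7, B7.4/5/8 and B7.6 against animal cells. With DESeq2, notochord against nerve cord had more called genes than either of B7.1/2 and B7.3/7 against animal cells. ENSCSAVG00000002295 was higher in notochord than nerve cord by a log2 of 3.92 (SE 0.72) without the drug and stood at -6.11 (SE 2.02) with it (difference -10.03, SE 1.89, adjusted p 0.0211), where the contrast with the drug was not itself called (adjusted p 0.124). ENSCSAVG00000000290 was higher in mesenchyme than muscle by 3.15 (SE 0.74) without it and stood at -5.95 (SE 1.69) with it (difference -9.10, SE 1.76, adjusted p 0.0185), again without a call in treated embryos (adjusted p 0.0945). Another called gene of each pair had no called contrast without the drug. For notochord against nerve cord, ENSCSAVG00000006134 went from 0.70 (SE 0.53) to -2.88 (SE 0.47, adjusted p 6.77e-05) with the drug. For mesenchyme against muscle, ENSCSAVG00000006303 went from 0.52 (SE 0.25) to -1.62 (SE 0.30, adjusted p 0.000946). The calls are therefore not all losses of an untreated contrast. Without 64-cell embryo 1, 2 or 3 the count for notochord against nerve cord was 0, 0 and 1, that for mesenchyme against muscle 0, 1 and 0, and that for A7.1/2/5/6 was 0 without embryo 3, while B7.1/2 gave 2 and 19 and B7.3/7 4 and 2 without embryo 1 or 2, and B7.6 gave 0 and 5. Without U0126 embryo 1 or 2 the counts were 135 and 73, 157 and 25, 15 and 15, and against animal cells 69 and 58 for B7.1/2, 66 and 32 for B7.3/7, 81 and 54 for A7.3/7, 30 and 23 for B7.4/5/8, and 9 and 10 for B7.6.

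Whole embryos with U0126 (reads) against untreated ones (UMIs) differed by 587 genes higher and 604 lower of 7844, with 352 and 784 by limma-trend. ENSCSAVG00000002246 went from 81.0 ± 29.5 CPM (n = 3) to 0 (n = 2), at least 553-fold lower (adjusted p 0.00139), and ENSCSAVG00000011378, the gene high in B7.7 mesenchyme, from 12.5 ± 12.1 to 0, at least 85.1-fold lower (adjusted p 0.0184). ENSCSAVG00000006763 rose from 0 to 46.8 ± 20.0 CPM, at least 129-fold (adjusted p 0.00457). Of the 77 genes that rose from the 8-cell to the 32-cell stage, 19 were lower with U0126, where 6.45 would be by chance, and 5 were higher, where 5.90 would. The count of 1191 was 38 and 39 without U0126 embryo 1 or 2, and 446 once the step from the 4-cell to the 8-cell stage, likewise from UMIs to reads, was subtracted.

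Within classes, treated cells (reads) and untreated cells (UMIs) differed by 498 of 5100 genes in A7.1/2/5/6 (284 higher, 214 lower) and by 940 of 6963 in animal cells (478 and 462), and no test separated treatment from the kind of count there. Other classes had fewer than 5 cells in some embryo and were not tested. In A7.1/2/5/6 the count was 169 and 165 without U0126 embryo 1 or 2 and 268 without 64-cell embryo 2, and in animal cells it was 100 and 117 without U0126 embryo 1 or 2.

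No share of the authors' classes was called different between treated and untreated embryos. The classes are named by blastomere and the cleavages follow a fixed lineage, so the number of blastomeres largely sets these shares. A7.1/2/5/6, for instance, held 8 cells in every embryo with and without U0126. Equal shares therefore do not speak to the fate of the cells. Notochord A7.3/7 made up 4.51 ± 2.34% of cells (n = 3) without and 5.72 ± 0.894% (n = 2) with U0126 (exact two-sided permutation p = 0.8), and animal cells 52.5 ± 2.15% and 51.6 ± 1.08% (exact p = 0.9). The smallest p of this design is 0.1. By profile, 6 of 8 untreated and 2 of 7 treated A7.3/7 cells resembled untreated A7.3/7 most (exact p = 0.2), and 7 of 8 and 1 of 7 with 1000 genes (exact p = 0.1). Of the 7 treated cells, 3 resembled endoderm A7.1/2/5 most, 1 trunk lateral A7.6 and 1 nerve cord A7.4/8. With 1000 genes these numbers were 3, 2 and 1. How the treated cells were given their class is not stated. Of the animal cells, 20.2 ± 4.49% resembled a neural class most without and 8.03 ± 2.79% with U0126 (exact p = 0.1, the smallest possible). Among untreated neural cells, 12 of 15 of a7.9/10/13 and 3 of 9 of b7.9/10 resembled their own class most. In all these matches by profile the treated cells were in reads and the untreated reference in UMIs. Treatment and the kind of count cannot be told apart there. Put in their nearest untreated class, treated cells of A7.3/7 changed by -1.77 percentage points instead of 1.21.

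Cells of an embryo were compared with each other to ask how far they had diverged at each stage. In reads, 10.3 ± 1.65% of genes varied between cells at the 8-cell stage (n = 3), 8.48 ± 2.18% at the 16-cell (n = 2) and 4.72 ± 0.211% at the 32-cell stage (n = 2). The number of variable genes did not fall with it, with means of 100, 189 and 170, since genes with enough counts grew from 922 to 1022 per embryo at the 8-cell to 3587 and 3593 at the 32-cell stage. In UMIs it was 1.89 ± 0.36% at the 64-cell and 2.92 ± 0.0664% at the 110-cell stage (n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). Thinned to 20000 counts, the step from the 8-cell to the 32-cell stage was 0.257 percentage points in place of a drop by 5.59. The percent also depends on the number of cells. It was 8 per embryo at the 8-cell, 16 at the 16-cell and 32 or 33 at the 32-cell stage. With fewer cells, a variance passes 2 times the mean more often by sampling alone. The fall in reads therefore does not show how far cells had diverged. The mean Spearman correlation between cells was 0.426 ± 0.00253 at the 64-cell and 0.449 ± 0.0114 at the 110-cell stage.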

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

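The tests in this part were chosen only after the results had been seen, apart from the interaction test for A7.1/2/5/6 against animal cells. In 255 cells the matrix total equalled the read number of the cell table, a column no comparison used, while the matrix is described as UMI counts; these cells make up all columns of the 1-, 8-, 16- and 32-cell stages and of the U0126 embryos. A test of the difference itself, the interaction of class and treatment, found that the contrast between A7.3/7 and A7.4/8 differed between untreated and treated embryos in 3 genes. The same test gave 2 genes for B7.3/7 against B7.4/5/8 and 1 gene for A7.1/2/5/6 against animal cells. Its largest counts by edgeR were 10 for B7.1/2 and 7 for B7.3/7 against animal cells, and it gave 1 each for A7.3/7, B7.4/5/8 and B7.6 against animal cells. With DESeq2, A7.3/7 against A7.4/8 had more called genes than either of B7.1/2 and B7.3/7 against animal cells. No embryo of the 1-cell or 2-cell stage stood apart from its group in the 14 gap tests, of which 0 passed. The other groups were not given this test.

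The first pattern was the large number of genes changed wherever reads were set against UMIs. The kind of count fits: 292 genes rose both from the 4-cell to the 8-cell stage and with U0126, where 71.0 would by chance, although this pair of comparisons shares no embryo and both go from UMIs to reads. Across genes, which are not independent replicates, changes with U0126 followed that step (Spearman rho 0.49), ran against the step from the 1-cell to the 2-cell stage, from reads to UMIs (-0.37), and had rho 0.03 with the step from the 1-cell to the 8-cell stage, which stays in reads, although 151 genes rose in that pair where 89.5 would by chance. Treatment could not be told apart from it: 446 genes were called with U0126 after subtracting the step from the 4-cell to the 8-cell stage. The read-count libraries are also the libraries with a repeat entry, so other differences of those libraries cannot be separated from the kind of count.

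The second pattern was the loss of the notochord contrast (A7.3/7 over A7.4/8) with U0126. The kind of count could not be ruled out: over animal cells, B7.4/5/8 kept 93.6% of its contrast and A7.4/8 77.5% in the same embryos, but B7.1/2 kept 58.8%, B7.3/7 47.8% and A7.1/2/5/6 40.3%. Depth stays open for treated embryo 2, whose total in A7.4/8 was 0.685 of the lowest untreated one. In A7.3/7 the treated embryos had 113170 and 87817 UMIs, within the 24589 to 126154 of untreated ones. Treated embryo 1 also lay within the untreated range in A7.4/8, with 243030 UMIs, yet its mean log2 contrast was 0.050. Untreated embryos stood at 0.727 or more, among them embryo 3 with the 24589 UMIs. These values argue against depth for treated embryo 1. Treatment stays possible but open: the exact two-sided permutation p was 0.1, the smallest that 3 and 2 embryos allow. A need of notochord for FGF and MEK signals is known biology, and no other inhibitor or rescue was measured here to test it.

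The third pattern was that some embryos of different stages shared gene levels: 64-cell embryo 3 and 110-cell embryo 1 had r 0.978 and no gene more than 8-fold apart, as did 110-cell embryos 2 and 3, while 64-cell embryos 1 and 3 had r 0.893 and 23 such genes (mean r 0.921 between and 0.919 within stages). Over those 23 genes, whose ratio in 64-cell embryos 1 and 3 is set by the way they were chosen, the log2 ratio of the 2 sides was 0.53 in 64-cell embryo 2 and -2.89, 4.24 and 3.89 in 110-cell embryos 1 to 3. Library batch stays open: only 1 library of the 110-cell stage held cells of more than 1 embryo (0 of 6 cells of embryo 1 and 7 of 7 of embryo 3 above 0), and its label lists 7 barcodes for the 13 cells. The cell classes sampled do not account for it, since the ratio was at least 3.28 in every class of 110-cell embryo 3. Shared parents may be the cause, but the labels give no parents and no biological explanation was tested.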

How the results depend on the processing

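Settings that left out the genes of neighbouring identifiers, that kept 1 kind of count or 2 classes in the fit, that subtracted the step from the 4-cell to the 8-cell stage, or that used 20, 100 or 1000 genes, and the tests on classes and held-out genes, were chosen only after the data had been seen. Of 735 recomputed values, 238 of them under alternatives fixed beforehand, 525 stayed the same, 185 moved, 1 was weaker, 0 were stronger and 24 reversed. The cause was not tested for those that moved or reversed unless stated. Values labelled the same can differ in size. For variation between cells and shares of cells, the smallest exact permutation p was 0.1 or more, so only a change of sign counted. The percent of variable genes differed by 5.09 between untreated 64-cell and U0126 embryos and by 24.4 thinned to 20000 counts, labelled the same. Counts of genes could also differ and keep this label. The 525 therefore do not show that sizes were stable. No paired analysis was possible because no embryo number occurs in more than 1 group. Tests of marker lists were not run because no identifier could be matched to a name, a replicate block was not run because groups share no embryo, and other clusterings were not run because the authors' classes were used. Where an embryo was left out of a group of 2, the lone embryo was assumed to vary like the other groups. Thinning left out 19 cells of the 110-cell stage, 7 of the 64-cell stage, 3 with U0126 and 1 of the 32-cell stage, which were under 10000 counts.

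A log2 threshold of 1, which by construction calls fewer genes, gave 1265 genes from the 1-cell to the 2-cell stage, 7 from the 2-cell to the 4-cell, 1130 from the 4-cell to the 8-cell, 700 from the 32-cell to the 64-cell, 1868 from the 1-cell to the 110-cell, 397 from the 4-cell to the 64-cell and 1060 from the 1-cell to the 8-cell stage. From the 2-cell to the 4-cell stage DESeq2 gave 55, RLE factors 6, any count 52, at least 50 counts 17, limma-trend 58 and UMI stages alone 2. From the 8-cell to the 16-cell stage DESeq2 gave 15, any count 24 and limma-trend 0 (344 at an unadjusted p under 0.05 by edgeR). From the 16-cell to the 32-cell stage any count gave 62, limma-trend 5 and read stages alone 11. From the 32-cell to the 64-cell stage limma-trend gave 486. From the 64-cell to the 110-cell stage DESeq2 gave 63, any count 63, limma-trend 40 and UMI stages alone 2. From the 8-cell to the 32-cell stage DESeq2 gave 157 and limma-trend 24. With U0126 DESeq2 gave 1905, and subtracting the step from the 4-cell to the 8-cell stage 446.

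Leaving out 1 embryo gave 2 to 17 genes from the 2-cell to the 4-cell stage, 1317 to 1644 from the 4-cell to the 8-cell, 3 to 14 from the 8-cell to the 16-cell, 22 to 38 from the 16-cell to the 32-cell, 526 to 1104 from the 32-cell to the 64-cell, 3 to 100 from the 64-cell to the 110-cell, 362 to 674 from the 4-cell to the 64-cell, 50 to 89 from the 8-cell to the 32-cell and 38 to 1488 with U0126. The steps from the 1-cell stage stayed within 1.5 times (2071 to 2409 to the 2-cell, 1590 to 2232 to the 8-cell and 2825 to 3339 to the 110-cell stage).

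Between classes, DESeq2 gave 8 genes for A against B, 99 for B6.3 against B6.4, 17 for A7.1/2/5 against A7.6, 1 for A7.1/2/5 against B7.1/2, 8 for b7.9/10 against epidermis, 3 for A8.7/8 against A8.15/16, 3 for B8.6 against A8.5/6/13/14 and 24 for b8.17-20 against posterior epidermis. Genes with any count gave 58 for B5.1 against B5.2, 1 for A5.1/2 against animal, 29 for B6.1 against B6.2, 77 for B6.3 against B6.4, 20 for B7.5 against B7.6 at the 64-cell stage, 45 for A7.1/2/5 against B7.1/2, 19 for a7.9/10/13 against epidermis, 15 for A8.7/8 against A8.15/16, 22 for B8.6 against B8.5 and 27 for anterior against posterior epidermis. With only the 2 classes in the fit, counts were 19 for B5.1 against B5.2, 52 for A5.1/2 against B5.1, 3 for A5.1/2 against animal, 27 for A6.1/3 against A6.2/4, 24 for B7.7 against B7.8, 21 for a7.9/10/13 and 24 for b7.9/10 against epidermis, 7 for B8.6 against B8.5, 4 for B8.6 against A8.5/6/13/14, 27 for B7.5 against B7.6 at the 110-cell stage, 59 for a8.17/18/19/20/25/26 against anterior epidermis, 79 for b8.17-20 against posterior epidermis and 49 for anterior against posterior epidermis. Without the genes of neighbouring identifiers, which by construction removes called genes, counts were 5 for A against B, 43 for B4.1 against animal, 7 for A5.1/2 against B5.1, 0 for A6.1/3 against A6.2/4, 0 for B6.1 against B6.2, 21 for A7.3/7 against A7.4/8, 15 for B7.3 against B7.4, 23 for B7.7 against B7.8 and 20 for A7.1/2/5 against A7.6; by edgeR 120 and 342 genes were under an unadjusted p of 0.05 where the count was 0.

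Leaving out 1 embryo gave 8 to 14 for A against B, 25 to 34 for A7.3/7 against A7.4/8, 19 to 29 for B7.3 against B7.4, 29 to 31 for B7.7 against B7.8, 7 to 18 for B7.5 against B7.6 at the 64-cell stage, 4 to 21 for A7.1/2/5 against A7.6, 3 to 34 for A7.1/2/5 against B7.1/2, 4 to 12 for a7.9/10/13 and 6 to 15 for b7.9/10 against epidermis. At the 110-cell stage it gave 30 to 62 for A8.5/6/13/14 against A8.7/8, 2 to 10 for A8.7/8 against A8.15/16, 6 to 19 for B8.6 against B8.5, 1 to 6 for B8.6 against A8.5/6/13/14, 8 to 25 for B8.7/8 against B8.15/16, 26 to 63 for B7.5 against B7.6, 25 to 39 for a8.17/18/19/20/25/26 against anterior epidermis and 7 to 16 between the epidermis classes. B4.1 against animal (47 to 52) and b8.17-20 against posterior epidermis (30 to 32) stayed within 1.5 times.

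For U0126 within A7.1/2/5/6 any count gave 783 genes, and leaving out 1 embryo 165 to 584, and 100 to 1063 in animal cells. The interaction gave 17 genes with DESeq2, 15 with any count and 0 to 135 leaving out 1 embryo for A7.3/7 against A7.4/8, 6, 18 and 0 to 157 for B7.3/7 against B7.4/5/8, and 3, 10 and 0 to 15 for A7.1/2/5/6 against animal. For B7.1/2 against animal it gave 8, 51 and 2 to 69, and for B7.3/7 against animal 6, 28 and 2 to 66. The percent of a contrast kept was 3.06 with 20 genes, 23.5 with 100 genes, 23.7 with a pseudocount of 40 and -3.73 without the genes of neighbouring identifiers for A7.3/7 over A7.4/8. For A7.4/8 over A7.3/7 it was 62.2 with 20 genes, 25.6 with 100 genes, 63.3 with a pseudocount of 40 and 15.6 without those genes. For B7.3/7 over B7.4/5/8 it was 4.15 with 20 genes, 67.5 with 100 genes, 77.7 with a pseudocount of 40, 15.9 after thinning and -0.677 without those genes; for A7.1/2/5/6 over animal it was 46.6 with 20 genes.

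Differences in the share of cells, U0126 minus untreated in percentage points, had no call and changed sign. With cells in their nearest class they were 1.10 for A7.1/2/5/6 and -1.77 for A7.3/7, and with 1000 genes 1.92, -2.81, -0.0963 for A7.4/8, -0.388 for B7.3/7 and 1.35 for B7.4/5/8. Leaving out 1 embryo gave -0.0617 to 2.24 for A7.3/7, -0.636 to 0.786 for A7.4/8 (-0.118 without U0126 embryo 2), -0.738 to 0.527 for B7.1/2 (0.317 without 64-cell embryo 1), -0.0476 to 0.411 for B7.3/7 (-0.0196 without U0126 embryo 2) and -1.67 to 0.371 for animal cells. Thinned to 20000 counts, genes per cell changed by -63.9 from the 2-cell to the 4-cell stage, the percent of variable genes by 2.79 from the 8-cell to the 16-cell and 0.257 from the 8-cell to the 32-cell stage, and the correlation between cells by 0.00640 from the 8-cell to the 16-cell stage. With at least 100 counts that correlation changed by -0.153 from the 16-cell to the 32-cell and -0.256 from the 8-cell to the 32-cell stage, and by -0.0958 in the latter thinned to 5000. With 1000 genes 9 classes of the 64-cell stage were nearest themselves, and without the 4 genes of the largest contrast at the 4-cell stage the posterior list had a mean of 0.52 (exact two-sided sign-flip p 0.147).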

Other observations

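The tests in this part were chosen only after the results had been seen. The most abundant gene, ENSCSAVG00000012509, took 14.7% of reads at the 1-cell stage and 9.41%, 9.04% and 7.98% at the 8-, 16- and 32-cell stages. In UMIs it took 3.07% and 2.74% at the 2- and 4-cell stages and 4.65% and 4.37% at the 64- and 110-cell stages. With U0126, the run of identifiers around it took 44.2 ± 1.02% of reads (SD, n = 2) in B7.4/5/8, 29.8 ± 1.53% in A7.4/8 and 8.64 ± 0.832% in A7.3/7, so muscle and nerve cord classes led there. The germline class B7.6 came next with 23.4% of reads. These shares are not set against those without the drug, since the run took 16.8% of reads in whole embryos with U0126 and 7.22% of UMIs in those without.

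The genes higher in posterior blastomeres at the 4-cell stage were also higher in the germline class of the 2 treated embryos (mean log2 2.21 ± 0.14). Whether the list as a whole is passed along the lineage of the germline stays open: its mean was higher than in the other classes in 12 later untreated embryos (exact two-sided sign-flip p 0.000488), but not higher than in the sister class B7.5 at the 110-cell stage (-0.01 ± 0.94). It may hold for only part of the list, since without the 4 genes of the largest contrast at the 4-cell stage the mean was 0.52 ± 1.14 and p 0.147, and over the sister class the whole list had p 0.0625. The mean of the 5 genes outside the run was higher than in the sister class in 9 of 9 embryos (exact two-sided sign-flip p 0.00391), although ENSCSAVG00000008691 among them was higher in 2 of 12 embryos over the other classes. How cells were given their class is not stated. If such genes served to assign the posterior and germline classes, higher values there would follow from the labels. These tests therefore do not decide on passage along the lineage. The genes of neighbouring identifiers do not account for the higher mean over the other classes, which was 3.65 without them. The mean of the whole list was higher than all random lists in 11 of the 12 embryos.

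A further hypothesis was that genes that rose during cleavage differ between classes more than other genes. It fits: the 330 genes that rose from the 4-cell to the 64-cell stage had a median shared variance between classes of 0.0582 in 110-cell embryos, against 0.0153 in random lists, and the 53 that also rose from the 8-cell to the 32-cell stage had 1.69. The same hypothesis for the 304 genes that fell from the 4-cell to the 64-cell stage found no backing, since 730 of 1000 random lists were as variable.

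Embryos were also divided in every other way that kept the group sizes, or in 100 ways where there were more, to see how many genes other divisions give. These fits held only the 2 groups compared, so their counts differ from those of the fit of all stages given above (1 in place of 17 from the 64-cell to the 110-cell stage). The true division gave the most genes from the 1-cell to the 2-cell stage (1 of 100 as high, 1719 genes against at most 325) and from the 1-cell to the 110-cell stage (1 of 100, 2588 against 17). The same held from the 1-cell to the 8-cell stage (1 of 100, 1783 against 55). From the 2-cell to the 4-cell stage it was 1 of 56, with 46 genes against 44. From the 4-cell to the 8-cell stage (2814 against 0) and from the 4-cell to the 64-cell stage (482 against 0) it was 1 of 10, too few for a share of 0.05. From the 64-cell to the 110-cell stage 3 of 10 divisions gave as many genes: the true one gave 1, and the division that put 64-cell embryo 1 with 110-cell embryos 2 and 3 gave 386, which points to structure between embryos other than the stage.

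In class contrasts within 3 embryos, the 2 labels can be exchanged in 4 ways, so the smallest share is 0.25, and the true labels gave the most genes (1 of 4) in each contrast. The true and the highest other count were 15 and 0 for A against B at the 4-cell stage and 70 and 0 for B4.1 against animal at the 8-cell stage. At the 64-cell stage they were 38 and 3 for A7.3/7 against A7.4/8, 34 and 0 for B7.3 against B7.4, 45 and 3 for B7.7 against B7.8, 35 and 0 for A7.1/2/5 against A7.6, 17 and 12 for A7.1/2/5 against B7.1/2, 10 and 0 for a7.9/10/13 against epidermis, and 15 and 3 for b7.9/10 against epidermis. At the 110-cell stage they were 70 and 2 for A8.5/6/13/14 against A8.7/8, 7 and 1 for A8.7/8 against A8.15/16, 14 and 5 for B8.6 against B8.5, 8 and 3 for B8.6 against A8.5/6/13/14, 26 and 2 for B8.7/8 against B8.15/16, and 66 and 9 for B7.5 against B7.6. In the ectoderm they were 39 and 0 for a8.17/18/19/20/25/26 against anterior-epidermis, 44 and 6 for b8.17-20 against posterior-epidermis, and 15 and 1 for anterior-epidermis against posterior-epidermis.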
